A study of Mus musculus with 8 samples.

How the data were processed

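RNA-seq of mouse testis was analysed in 8 libraries, 4 with the genotype label CTL and 4 with the label N6amt1-SKO. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra RNA kit that does not mark strand. The same protocol names heart ventricles, while the tissue label is testis. Per the submitters' processing notes, the tools were CASAVA, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, with genome build mm10. Whether read pairs, overlapping genes or multiply mapped reads were counted is not given in the sources used here.

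The deposited file is a single table of gene symbols by library. Its values are a score, not raw counts: the authors deposited read counts that had been multiplied by a factor per library and rounded to whole numbers. This was read from the values. In the 6 libraries with a factor above 1, 100.0% of values up to 1000 were the rounded multiple of a whole number, where 43.1% to 68.0% would be by chance. The factors, estimated from the comb of gaps, were 0.3944, 0.4579, 1.4703 and 1.7881 in CTL 1 to 4 and 1.545, 2.2046, 1.7214 and 2.3221 in SKO 1 to 4. In CTL 1 and CTL 2 the factor lies below 1 and rests on a weaker signal. Column totals divided by these factors give about 40.6 to 258 M reads per library. The scaling method is not given in the sources used here. The lowest row maximum was 95, so genes below some floor had been left out of this table. 204 rows are identical to another row, as overlapping or near-identical genes give when reads are counted for both. Since the kit does not mark strand, overlapping genes on opposite strands cannot be told apart either. Exon overlaps of the named genes were taken from GENCODE M21. Beyond those given beside the genes, 18.1% of the exon bases of Uchl1 and 16.8% of those of Sox17 overlap an opposite-strand transcript that is not in the table.

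Because the values are not raw counts, the negative binomial count tests planned before the data were examined were replaced by limma. Genes with a value of at least 25 in at least 4 libraries were kept, which left 17066 of 17121. Values were divided by TMM factors (trims of 30% and 5%), written out for this purpose. They were taken as log2(value + 5) and fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean and no covariate. Fold changes are on that log2(value + 5) scale, which understates the change of low genes, and are differences of mean log2 values. Means and SDs are of the normalised values. The filter, the added constant of 5 and the 18S limit used below were set after the values had been seen. Tests are two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A planned test against a fold of 1.5 was run with limma.

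The 25 gene lists were fixed before the data were examined: undifferentiated and differentiating spermatogonia, synaptonemal complex and meiotic cohesin, meiotic recombination, meiotic entry and prophase regulators, pachytene and later spermatocyte genes, G2/M and meiotic division, piRNA pathway, round spermatid and acrosome, elongating spermatid and sperm tail, cilium and axoneme, meiotic DNA damage response and sex chromosome silencing, p53 targets and apoptosis, the N6AMT1 and TRMT112 network, translation termination and nonsense-mediated decay, DNA methylation and 6-methyladenine enzymes, retinoic acid pathway, and markers of Sertoli, Leydig, peritubular myoid, macrophage, endothelial, red blood, epididymis and heart muscle cells. Each list with at least 5 tested members (24 lists) was compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation. None of the list calls held at 0.05 with the estimated correlation, nor did the X-linked and Y-linked calls. The list score is the mean log2 value of the members in a library, compared by an exact permutation test over the 70 assignments of 4 and 4. 6 pairs of lists share between 1 and 3 tested genes. Chromosomes and coordinates come from the RefSeq table of GRCm38.p6, the assembly of which mm10 is the browser name. It holds 16891 of the symbols, and Brme1 and Meiosin are not among them.

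The genes named in the text were set by a rule fixed before the data were examined: N6amt1, Trmt112 and Etf1, 12 fixed stage and cell type genes, up to 2 risen and 2 fallen members of each list with the largest changes (or the most abundant member if none passed), and the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap of the groups, leaving out clone and model names. It gave 88 genes.

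No libraries were duplicates: the lowest chi-square per gene between any 2 libraries was 36.4. Pearson correlations of log2 values lay between 0.94 and 0.99 within CTL and between 0.96 and 0.98 within SKO-labelled libraries. Across the groups they covered nearly the same range, from 0.9356 (CTL 4 and SKO 1) to 0.983 (CTL 1 and SKO 1). CTL 1 thus correlated better with SKO 1 than with CTL 3 (0.9703) or CTL 4 (0.9485). A technical library set was defined by an 18S share above or below 0.5%, which separates CTL 3, CTL 4 and SKO 4 from the other 5.

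The fit was tested on simulated tables made from the 17066 genes, the real depths, factors and spread, with 200 genes changed between N6amt1-SKO and CTL. It found 4.48% of genes changed 1.5-fold, 38.8% of those changed 2-fold and 87.9% of those changed 4-fold, with 6 false calls. The simulation changed far fewer genes than were called in the data, so these shares set no limit for the real comparison. In a further simulated table, with a single list raised 1.5-fold, 0 of 20 unchanged lists were called by camera. These lists were random and the noise was drawn independently for each gene. The estimated correlation of the real lists reached 0.694 (elongating spermatid genes), so this result does not bear on false calls among them.

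Alternatives planned before the data were examined were median-ratio, upper quartile, library total and Sertoli-based factors, no filter, and a mean of at least 1 CPM. Also planned were limma-voom, the replicate number as a block, leaving out each library, an estimated set correlation and fry. The division of the values by the factor before limma-voom was set only after the factors had been found in the values. Added after seeing the data were pseudocounts of 1 and 50, the library set as a term, each library set alone, leaving out the 2 deepest libraries, and a correction of each library for transcript length and GC content (GENCODE M21, available for 96.2% of the tested genes).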

Results

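Gene expression was measured by RNA-seq in 8 libraries of mouse testis, 4 labelled CTL and 4 labelled N6amt1-SKO. The series asks how N6AMT1 acts in the making of sperm. N6AMT1 is a methyltransferase that works in a complex with TRMT112 and methylates the translation termination factor eRF1, the product of Etf1. The labels do not spell out SKO, give no age, and do not state that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The extraction protocol names heart ventricles, whereas the tissue label of each library is testis. Germ cell genes were abundant in all 8 libraries, which argues against heart as the main tissue. Normalised values were 29479 to 62532 for the spermatocyte gene Piwil1 and 6325 to 87906 for the protamine gene Prm1. The median deposited value of a library lay between 1359 and 2110. Libraries are named below by group and replicate, and a rise means a higher value in the 4 libraries labelled N6amt1-SKO (SKO-labelled).

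The deposited table held whole numbers for 17121 genes, with column totals between 94.2 and 103 M (M for 10 to the power of 6). These were read counts multiplied by a factor per library and rounded. The reads behind them came to about 258, 225, 70.1 and 57.4 M in CTL 1 to 4, and 65.6, 46.7, 58.8 and 40.6 M in SKO 1 to 4. CTL 1 and CTL 2 were thus the most deeply sequenced. The libraries also differed in ribosomal RNA. 18S took 0.73% and 0.72% of the values in CTL 3 and CTL 4 and 0.97% in SKO 4, against 0.17% to 0.27% in the other 5 libraries. This split, which crosses the groups, was treated as a technical library set. Mitochondrial genes took 1.13% to 1.99% of the values in CTL libraries and 2.11% to 4.53% in SKO-labelled libraries.

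N6amt1 (GRCm38, chromosome 16, 87354185 to 87368649) was not lower in the SKO-labelled libraries. Its normalised values were 475, 433, 629 and 514 in CTL 1 to 4 and 586, 557, 561 and 625 in SKO 1 to 4, with 252 to 1184 reads behind each. The means were 513 ± 84.6 (SD, n = 4) and 582 ± 31.1 (SD, n = 4), a log2 fold change of 0.19 with a standard error of 0.17 and a limma adjusted p of 0.437. The labels do not say which part of the gene was targeted, and a value summed over the whole gene cannot separate a deleted exon from the remaining ones. The measurement therefore does not check the genotype labels. Its partner Trmt112 had means of 1337 ± 392 and 1706 ± 60.3 (SD, n = 4 each; limma adjusted p = 0.19), and 33.2% of its exon bases overlap Prdx5. Etf1 had means of 16297 ± 3031 and 15852 ± 2459 (SD, n = 4 each; limma adjusted p = 0.91).

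**Figure D1:**
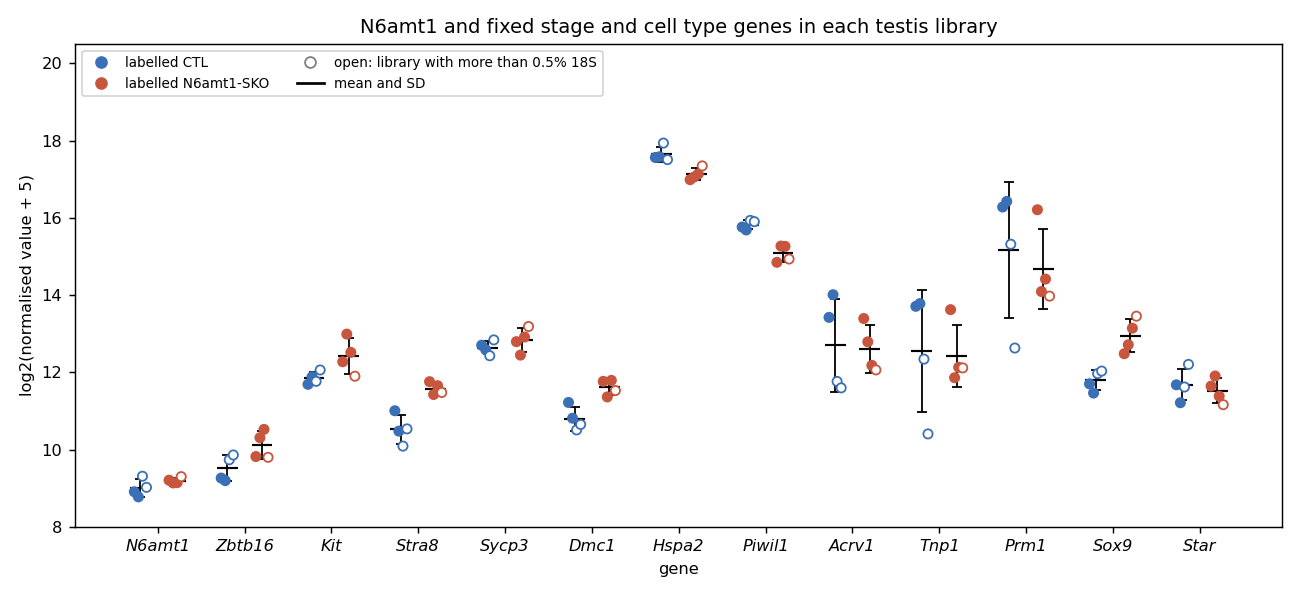
Normalised values of N6amt1 and of 12 stage and cell type genes on a log2(value + 5) axis, 1 point per library, with the mean and SD of each group as a bar. N6amt1 lay between 433 and 629 in CTL and between 557 and 625 in SKO-labelled libraries, while Acrv1, Tnp1 and Prm1 spread widely within both groups.

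The comparison of the groups asks which transcripts differ in testis between the genotype labels. Sertoli cell markers (22 of 34 risen), part of the p53 and apoptosis genes (13 of 31) and part of the X-linked genes (213 of 726) were higher in the SKO-labelled libraries. Cilium and axoneme genes (21 of 38 fallen), part of the piRNA pathway genes (12 of 25, with 2 risen) and part of the pachytene and later spermatocyte genes (9 of 29) were lower. None of these set calls held with an estimated correlation (adjusted p = 0.299 for each list and adjusted p = 0.081 for X-linked genes). Of 17066 genes tested, 2038 rose and 1354 fell at a limma adjusted p below 0.05. At least 2-fold changes were called for 444 risen and 163 fallen genes. The groups did not overlap for 26.1% of genes, where chance gives 2.86% on average. Genes vary together, so the share for a single grouping can lie far from that average. It was not computed for other groupings, so the 26.1% is not a test.

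These counts depend on the scaling and on single libraries. Risen genes made up 60.1% of calls with TMM factors, 49.2% with median-ratio factors, 67.4% with upper quartile factors, 91.5% with library totals and 0.236% with factors that hold the Sertoli markers level. The median log2 fold change of all genes was 0.04 with TMM factors, 0.33 with library totals and -0.85 with Sertoli factors, so directions below are relative to the bulk of genes. Without SKO 3 no gene was called by limma (0 genes, smallest adjusted p 0.0567, with 4788 genes at an unadjusted p below 0.05). Risen and fallen counts were 686 and 542 without CTL 3, 812 and 468 without SKO 1, and 823 and 503 without SKO 2. Without CTL 2 the risen count was 1108. A limma test against a fold of 1.5 called 0 genes, with 688 at an unadjusted p below 0.05. Within the 5 libraries with less 18S, 3202 genes rose and 2291 fell. Within the 3 libraries with more 18S, which hold a single SKO-labelled library, 35 rose and 231 fell.

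The largest rises among genes whose groups did not overlap were those of Erdr1, at the pseudoautosomal end of the X chromosome (5.38-fold, from 110 ± 47.6 to 642 ± 316, SD, n = 4 each), and Tnfrsf12a, the receptor of the cytokine TWEAK (4.92-fold). Dlk1, a paternally expressed Notch ligand homologue, rose 3.51-fold, Sncb 3.50-fold, Wfdc10 3.43-fold, Igfbp3, which binds insulin-like growth factors, 3.28-fold, Scara3 3.16-fold and Ppp2r2c 3.14-fold. The largest falls were those of Fat3 (3.30-fold lower, from 2730 ± 1504 to 768 ± 282, SD, n = 4 each), Dnah8 (2.86-fold), Pcdha2 (2.81-fold), Camk1g (2.76-fold), Dnah17 (2.76-fold), Dnah12 (2.75-fold), Dnah6 (2.70-fold) and the calcium channel gene Cacna1h (2.59-fold). Pcdha2 shares 53.3% of its exon bases with other protocadherin alpha genes, so its own value is uncertain. The size of these falls differed between the library sets. Within CTL, library deviations also went with transcript length, with Spearman correlations of -0.348, -0.281, 0.243 and 0.421 in CTL 1 to 4. In SKO 1 to 4 these were -0.39, 0.154, 0.0706 and -0.0963. Across genes the log2 fold change had a Spearman correlation of -0.0765 with length. The log2 fold changes of Dnah8, Dnah17, Dnah12 and Dnah6 were -0.72, -0.76, -0.78 and -0.80 within the lower 18S libraries and -2.26, -2.27, -2.17 and -2.00 within the higher 18S libraries. Those of Fat3, Pcdha2, Camk1g and Cacna1h were -1.05 (limma adjusted p = 0.0693), -1.08, -0.75 and -0.81 within the lower and -2.56, -2.02, -2.78 and -1.96 within the higher 18S libraries. Among the rises, Tnfrsf12a and Sncb went by 1.56 and 1.02 within the lower 18S libraries and by 2.74 and 2.60 within the higher. Igfbp3 and Ppp2r2c were among those that rose less in the higher 18S libraries. Igfbp3 had 272 and 380 in CTL 3 and 4 and 602 in SKO 4, against 494 and 422 in CTL 1 and 2 and 1221 to 2054 in SKO 1 to 3. Ppp2r2c had 422 and 881 in CTL 3 and 4 and 1240 in SKO 4, against 854 and 461 in CTL 1 and 2 and 1648 to 3178 in SKO 1 to 3. limma adjusted p-values of these 16 genes lay between 0.0123 and 0.0334.

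Sertoli cells, the somatic cells that nurse the germ cells, showed the most uniform shift. Of 34 Sertoli markers 22 rose, 0 fell and 12 did not pass, and 28 rose when adjusted over the list alone. Amh, the anti-Müllerian hormone gene (chromosome 10, 80805240 to 80807679), went from 921 ± 517 to 2615 ± 832 (SD, n = 4 each; limma adjusted p = 0.0284). Shbg, whose product binds sex hormones, went from 1330 ± 574 to 3638 ± 896 (SD, n = 4 each; limma adjusted p = 0.0168), and Sox9, a Sertoli cell transcription factor (chromosome 11, 112782210 to 112787757), from 3580 ± 628 to 8164 ± 2457 (SD, n = 4 each; limma adjusted p = 0.0147). The list's median log2 fold change was 0.93, and all 4 SKO-labelled libraries scored above all CTL libraries (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give; 0.0858 adjusted over the 24 lists tested). The set test gave an adjusted p of 5.68e-11 with a preset correlation, but an adjusted p of 0.299 with an estimated correlation. The median was 0.89 within the lower 18S libraries and 0.91 within the higher 18S libraries.

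Other somatic markers moved less. Of 19 peritubular myoid and smooth muscle markers 7 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.49; set test adjusted p = 0.00556, and adjusted p = 0.368 with an estimated correlation). Tcf21 rose 2.10-fold and Myl9, a smooth muscle myosin light chain, 1.92-fold. Of 22 macrophage and immune markers 5 rose and 0 fell, also when adjusted over the list alone (median 0.65; set test adjusted p = 0.00325, and adjusted p = 0.464 with an estimated correlation; exact two-sided permutation p of the score = 0.0571, n = 4 each). The MHC class II genes H2-Eb1 and H2-Aa rose 2.89-fold and 2.56-fold. Within the higher 18S libraries, with a single SKO-labelled library, the medians were 0.31 for myoid and 0.41 for macrophage markers. The myoid list lost its call without the 2 most deeply sequenced libraries (median 0.28, set test adjusted p = 0.0809). Of 18 Leydig cell markers 2 rose and 0 fell, also when adjusted over the list alone, and the list did not pass (median 0.21, adjusted p = 0.37). Hsd3b1, which makes steroid hormones, rose 2.05-fold and Fdxr 1.60-fold, while Star, the cholesterol carrier of Leydig cells, had means of 3372 ± 979 and 2992 ± 669 (SD, n = 4 each; limma adjusted p = 0.668). Of 17 endothelial markers 2 rose (Robo4, 2.25-fold, and Cldn5, 1.70-fold) and 1 fell (Sox17, 1.65-fold lower), with the same counts when adjusted over the list alone (median 0.12, set test adjusted p = 0.653).

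Part of the markers of differentiating spermatogonia were higher. Of 16 genes 5 rose and 0 fell, and 7 rose when adjusted over the list alone (median log2 fold change 0.51; set test adjusted p = 0.00358, and adjusted p = 0.411 with an estimated correlation). 3 of 4 SKO-labelled libraries scored above all CTL libraries (exact two-sided permutation p = 0.0571). Stra8, the retinoic acid response gene that marks the entry into meiosis (chromosome 6, 34920163 to 34939344), rose 2.07-fold, from 1508 ± 400 to 3066 ± 329 (SD, n = 4 each; limma adjusted p = 0.0137), and Sohlh1, a spermatogonial transcription factor, rose 1.93-fold. Kit had means of 3702 ± 424 and 5682 ± 1827 (SD, n = 4 each) and did not pass (limma adjusted p = 0.0905). The list's median was 0.59 within the lower 18S libraries and 0.18 within the higher 18S libraries, which hold a single SKO-labelled library. Of 15 markers of undifferentiated spermatogonia 3 rose and 0 fell, also when adjusted over the list alone, and the list did not pass (median 0.24, set test adjusted p = 0.384). Uchl1 rose 1.91-fold and Ret 1.77-fold, while Zbtb16 had means of 740 ± 171 and 1128 ± 285 (SD, n = 4 each; limma adjusted p = 0.0916). Of 18 retinoic acid pathway genes 5 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (median 0.58; set test adjusted p = 0.0391, and adjusted p = 0.411 with an estimated correlation). The retinol transporter gene Stra6 rose by a log2 fold change of 0.84, whereas Rdh11 was 1.85-fold lower. This list just missed the threshold, at nearly the same size, without CTL 4 (median 0.54, adjusted p = 0.0541) and without SKO 3 (median 0.53, adjusted p = 0.0704). With library totals it did not pass (median 0.54 relative to all genes, adjusted p = 0.103), and within the higher 18S libraries the median was 0.29.

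Genes of meiotic prophase went both ways. Among 15 regulators of meiotic entry and prophase 4 rose and 4 fell, also when adjusted over the list alone (median log2 fold change -0.22, set test adjusted p = 0.384). Stra8 and its partner Meiosin (1.91-fold) rose. Zfp541 and Kctd19, which act together in pachytene spermatocytes, were 1.87-fold and 1.85-fold lower. Of 21 genes of the synaptonemal complex and meiotic cohesin, the Six6os1 gene (listed as 4930447C04Rik) rose 1.71-fold and the cohesin gene Stag3 was 2.09-fold lower, with the other 19 not passing and the same 1 risen and 1 fallen when adjusted over the list alone (median -0.08, set test adjusted p = 0.481). Sycp3, an axial element protein gene, had means of 6404 ± 771 and 7419 ± 1547 (SD, n = 4 each; limma adjusted p = 0.448), and 52.2% of its exon bases overlap Chpt1. Of 35 meiotic recombination genes 2 rose and 3 fell, and 1 rose and 0 fell when adjusted over the list alone (median 0.18, set test adjusted p = 0.653). The recombinase gene Dmc1 rose 1.76-fold, from 1806 ± 407 to 3146 ± 436 (SD, n = 4 each; limma adjusted p = 0.0191), and the Top6bl gene, listed as Gm960, rose 1.61-fold. Brme1 was 1.62-fold lower and Cntd1 1.38-fold lower, but 70.2% of the exon bases of Cntd1 overlap Becn1 on the opposite strand. Of 30 genes of the meiotic DNA damage response and sex chromosome silencing 4 rose and 2 fell, also when adjusted over the list alone (median -0.08, set test adjusted p = 0.481), with rises of Chek2 (1.88-fold) and Scml2 (1.68-fold) and falls of Rpa1 (1.71-fold lower) and Trim28 (1.40-fold lower).

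Part of the genes of pachytene and later spermatocytes were lower. Of 29 genes 0 rose and 9 fell, and 10 fell when adjusted over the list alone (median log2 fold change -0.52; set test adjusted p = 4.05e-06, and adjusted p = 0.299 with an estimated correlation). The scores overlapped, with 3 of 4 SKO-labelled libraries below all CTL libraries (exact two-sided permutation p = 0.0571). Piwil1, the piRNA-binding protein of pachytene cells (chromosome 5, 128736071 to 128755474), went from 57969 ± 4655 to 34862 ± 5243 (SD, n = 4 each; limma adjusted p = 0.015), Adam2 was 1.75-fold lower, and the chaperone gene Hspa2 went from 206485 ± 29680 to 144018 ± 15922 (SD, n = 4 each; limma adjusted p = 0.0467). The list's median was -0.66 within the lower and -0.22 within the higher 18S libraries, which hold a single SKO-labelled library. Of 34 G2/M and meiotic division genes 3 rose and 5 fell, and 4 rose and 7 fell when adjusted over the list alone. The median was -0.22 (set test adjusted p = 0.065, and adjusted p = 0.637 with an estimated correlation). This list passed as lower without CTL 1 (adjusted p = 0.0337), without CTL 2 (adjusted p = 0.0165), without SKO 4 (adjusted p = 0.0169), without the 2 most deeply sequenced libraries (adjusted p = 0.00531) and after the length and GC correction (adjusted p = 0.0448). Espl1 (separase) fell by a log2 fold change of 0.84 and Aurka was 1.69-fold lower, and Cks1b and Ccna2 rose 1.83-fold and 1.53-fold, although 12.5% of the exon bases of Ccna2 overlap Exosc9.

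Of 25 piRNA pathway genes 2 rose and 12 fell, and 13 fell when adjusted over the list alone (median log2 fold change -0.47; set test adjusted p = 0.000235, and adjusted p = 0.299 with an estimated correlation). All 4 SKO-labelled libraries scored below all CTL libraries (exact two-sided permutation p = 0.0286; 0.0858 adjusted over the 24 lists). Tdrd6, a tudor protein of the chromatoid body (chromosome 17, 43615334 to 43631846), was 2.22-fold lower and Spocd1 1.82-fold lower. The fall of Tdrd6 was larger among the higher 18S libraries, with 133460, 140960, 260140 and 244570 in CTL 1 to 4 and 76011 to 88661 in SKO-labelled libraries. Piwil4, which works in the fetal and spermatogonial piRNA pathway, rose 2.92-fold at low values (42.5 ± 21.8 and 123 ± 23.8, SD, n = 4 each), and Tex19.1 rose by a log2 fold change of 0.59. The list's median was -0.38 within the lower and -0.59 within the higher 18S libraries.

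Cilium and axoneme genes showed the clearest fall. Of 38 genes 0 rose and 21 fell, and 29 fell when adjusted over the list alone. The axonemal dynein heavy chain gene Dnah8 (chromosome 17, 30626935 to 30875762) had means of 441063 ± 270189 in CTL and 133929 ± 25458 in SKO-labelled libraries (SD, n = 4 each; limma adjusted p = 0.0334), and Dnah17 (chromosome 11, 118021723 to 118130719) 145576 ± 71711 and 48160 ± 7964 (SD, n = 4 each; limma adjusted p = 0.0198). The list's median log2 fold change was -0.74, with all 4 SKO-labelled libraries below all CTL libraries (exact two-sided permutation p = 0.0286; 0.0858 adjusted over the 24 lists). The set test gave an adjusted p of 3.36e-13 with a preset correlation and an adjusted p of 0.299 with an estimated correlation. The median was -0.68 within the lower 18S libraries and -0.63 within the higher 18S libraries.

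**Figure D2:**
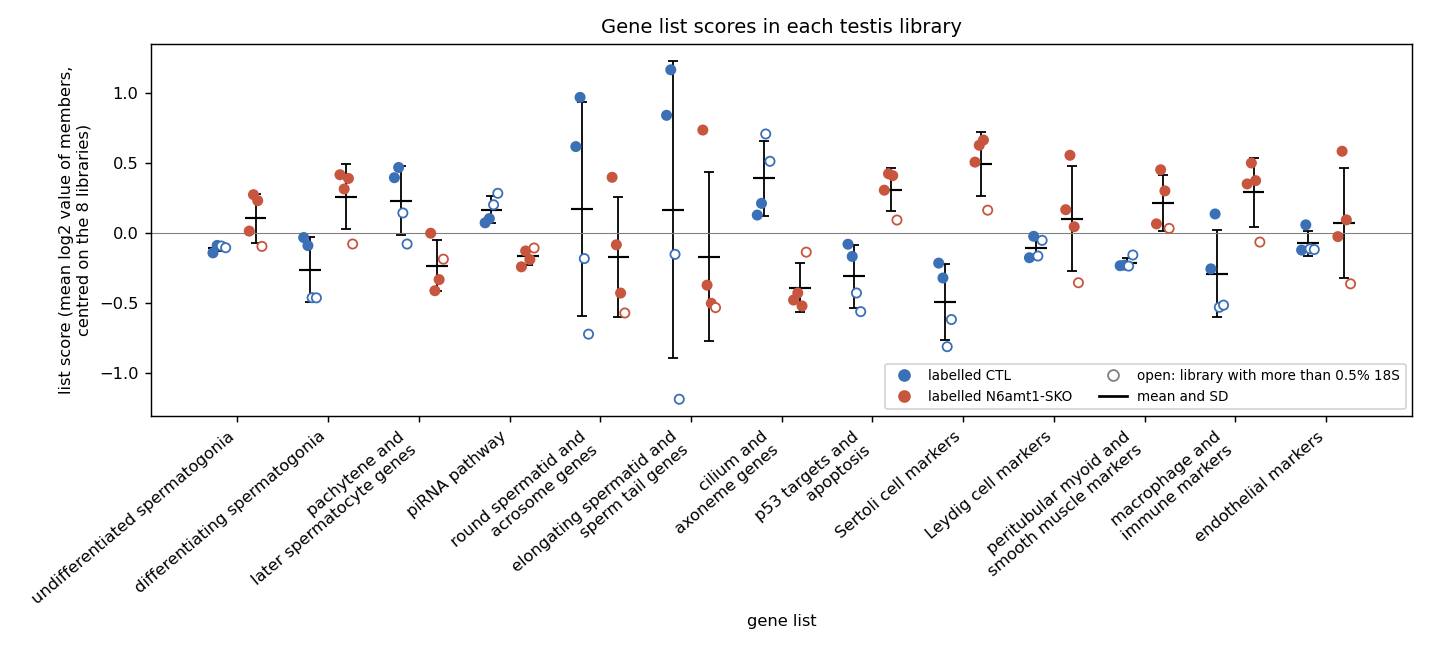
Mean log2 value of the members of 13 fixed gene lists in each library, centred on the 8 libraries, 1 point per library, with the mean and SD of each group as a bar and open points for the 3 libraries with more 18S. The Sertoli list scored between -0.81 and -0.21 in CTL and between 0.16 and 0.66 in SKO-labelled libraries, and the elongating spermatid list ran from -1.18 to 1.16 within CTL.

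Spermatid genes varied more within the groups than between them. Of 36 round spermatid and acrosome genes 0 rose and 5 fell, and 4 fell when adjusted over the list alone (median log2 fold change -0.25; set test adjusted p = 0.000838, and adjusted p = 0.611 with an estimated correlation). Rfx2, a transcription factor of spermatids, was 1.96-fold lower, and Dpy19l2 was 1.81-fold lower. Of 41 elongating spermatid and sperm tail genes 0 rose and 2 fell, also when adjusted over the list alone (median -0.36; set test adjusted p = 0.00556, and adjusted p = 0.665 with an estimated correlation), namely Spag16 (1.97-fold lower) and Gk2 (1.73-fold lower). The scores of both lists did not separate the groups (exact two-sided permutation p = 0.486 and 0.657, n = 4 each). The protamine gene Prm1 had values of 79527, 87906, 40784 and 6325 in CTL 1 to 4 and 75725, 17442, 21816 and 16063 in SKO 1 to 4 (limma adjusted p = 0.702). Tnp1 and Acrv1, a transition protein and an acrosomal protein gene, did not pass either (limma adjusted p = 0.919 and 0.924). Within the lower 18S libraries the medians were -0.86 for round and -1.15 for elongating spermatid genes. Within the higher 18S libraries, which hold a single SKO-labelled library, they were -0.04 and 0.18. Without the 2 most deeply sequenced libraries both medians turned to 0.24 and 0.46, with no call (adjusted p = 0.954 and adjusted p = 0.398). The elongating spermatid call also ended without CTL 1 alone (median -0.12, adjusted p = 0.114) and without CTL 2 alone (median -0.07, adjusted p = 0.26). With Sertoli factors neither spermatid list passed (adjusted p = 0.304 and adjusted p = 0.822).

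Part of the p53 response and apoptosis genes were higher. Of 31 genes 13 rose and 1 fell, and 18 rose and 3 fell when adjusted over the list alone (median log2 fold change 0.58; set test adjusted p = 0.000235, and adjusted p = 0.299 with an estimated correlation). All 4 SKO-labelled libraries scored above all CTL libraries (exact two-sided permutation p = 0.0286; 0.0858 adjusted over the 24 lists). Pmaip1, which encodes the BH3-only protein NOXA (chromosome 18, 66458604 to 66465558), rose from 402 ± 58.6 to 1101 ± 57.7 (SD, n = 4 each; limma adjusted p = 0.0123), and Gadd45a, a growth arrest gene with 337 exon bases that overlap E230016M11Rik, rose 2.79-fold. Zmat3, a further p53 target, was 1.52-fold lower. In this list, as in the Sertoli list, CTL 3 and CTL 4 scored lowest in CTL and SKO 4 lowest in the SKO-labelled libraries. The median was 0.65 within the lower and 0.52 within the higher 18S libraries.

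Among 11 genes of the N6AMT1 and TRMT112 network 3 rose and 1 fell, also when adjusted over the list alone (median log2 fold change 0.35, set test adjusted p = 0.222). All 4 SKO-labelled libraries scored above all CTL libraries for this list (exact two-sided permutation p = 0.0286, or 0.0858 adjusted over the 24 lists), and the rotation test fry gave an adjusted p of 0.00261. Unlike camera, fry tests a list against no change and not against the other genes. Thumpd2 rose 2.03-fold and Gspt2, an X-linked copy of the gene of the termination factor eRF3, 2.01-fold, while Thumpd3 was 1.55-fold lower. Of 20 genes of translation termination and nonsense-mediated decay 2 rose and 3 fell, and 2 rose and 5 fell when adjusted over the list alone. The median was -0.25 (set test adjusted p = 0.0687, and adjusted p = 0.555 with an estimated correlation). This list passed as lower without CTL 1 (adjusted p = 0.0337), without CTL 2 (adjusted p = 0.0298), without SKO 4 (adjusted p = 0.0466), without the 2 most deeply sequenced libraries (adjusted p = 0.0108) and after the length and GC correction (adjusted p = 0.0448). Mcts1 rose 2.11-fold, and the decay factor gene Smg5 was 1.82-fold lower. Of 20 DNA methylation and 6-methyladenine enzymes 3 rose and 0 fell, also when adjusted over the list alone (median 0.33, set test adjusted p = 0.361), among them the methylcytosine dioxygenase genes Tet2 (2.08-fold) and Tet3 (1.64-fold).

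X-linked genes, which are silenced in pachytene spermatocytes, were read apart. Of 726 X-linked genes tested 213 rose (29.3%) and 6 fell (0.826%), against 11.3% risen and 8.28% fallen of 16045 autosomal genes. The median log2 fold change was 0.49 for the X chromosome, and between -0.05 and 0.07 for the 19 autosomes. The set test gave an adjusted p of 4.28e-11 with a preset correlation and an adjusted p of 0.081 with an estimated correlation. All 4 SKO-labelled libraries scored above all CTL libraries (exact two-sided permutation p = 0.0286), and the median was 0.58 within the lower and 0.47 within the higher 18S libraries. Of 54 Y-linked genes 1 rose and 0 fell, with a median of -0.30 and a set test adjusted p of 0.0366 (adjusted p = 0.287 with an estimated correlation). Identical rows were not merged for this test, so gene copies that share reads would count more than once. The Y-linked call ended without CTL 1 (median -0.28, adjusted p = 0.0809), without CTL 2 (median -0.32, adjusted p = 0.14) and without SKO 2 (median -0.18, adjusted p = 0.123). Within the higher 18S libraries, with a single SKO-labelled library, the median was 0.50.

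**Figure D3:**
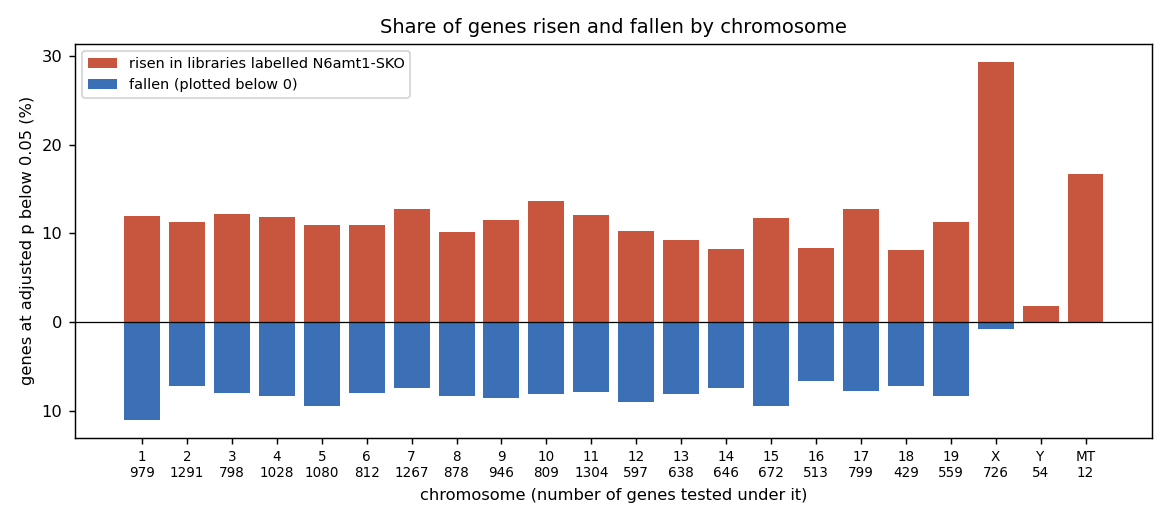
Percentage of tested genes of each chromosome that rose (upper bars) or fell (lower bars) at a limma adjusted p below 0.05, with the number of genes tested under each chromosome name. On the X chromosome 29.3% rose and 0.826% fell, while on autosomes 11.3% rose and 8.28% fell.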

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

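The search for outlying libraries was set before the data were examined. In each group of 4, a library was singled out when its gap to the nearest other library took up most of the group's range. The test covered 234 groups of values, the named genes and list scores in either genotype group, and singled out 10, where chance singles out about 1 in 20, so these cases are no more than chance gives and are listed only as values.

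In SKO 1, late spermatid transcripts were singled out. Its Prm1 value was 75730, against 16060 to 21820 in the others, and its Tnp1 value was 12600, against 3711 to 4479. Its score for elongating spermatid and sperm tail genes was 0.73, against -0.53 to -0.37. In SKO 4 it was mitochondrial genes, with a score of 1.26 against -0.06 to 0.05 in the others. Its Shbg value was 2300, against 3972 to 4145, and its Chek2 value was 384.6, against 466.1 to 482.3.

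In the remaining cases the Hspa2 value of CTL 3 was 250600, against 186200 to 195900 in the other CTL libraries. The Ccna2 value of SKO 2 was 2611, against 1973 to 2076. The peritubular myoid score of CTL 4 was -0.16, against -0.24 to -0.23, and the endothelial score of CTL 2 was 0.059, against -0.12 to -0.11.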

How the results depend on the processing

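Alternatives added after seeing the data are the pseudocounts, the library sets, the removal of the deepest libraries and the length and GC correction. The division by the factor before limma-voom was also set then. The planned count tests were not run: edgeR and DESeq2 were not used, because the values are not raw counts. Unless a cause is given, the cause was not tested.

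N6amt1 stayed uncalled under every alternative run, with log2 fold changes from -0.02 to 0.32. With library totals and Sertoli factors, its value and its test were taken relative to the median of all genes. Its call without that shift is not given here. X-linked genes stayed higher and past the threshold under every alternative run except the estimated correlation (median 0.49, adjusted p = 0.081). Risen and fallen genes were 4885 and 456 with library totals and 24 and 10158 with Sertoli factors, which shift all genes together by construction, and the corresponding 2-fold counts were 1771 and 30, and 6 and 6445. Sertoli factors left 3 lists called down. A test against a fold of 1.5 left 0 and 0 of the 2-fold genes (688 at an unadjusted p below 0.05). A pseudocount of 50 left 265 2-fold rises. Fallen genes were 2210 with the library set as a term, 2153 with the length and GC correction and 2326 without the 2 deepest libraries, where 2-fold counts were 931 and 895. Within the lower 18S libraries 3202 rose and 2291 fell. Within the higher 18S libraries, with fewer libraries and a lone SKO-labelled library assumed to vary like CTL, 35 rose (35 at least 2-fold) and 231 fell, and 3 lists were called up and 2 down. Leaving out 1 library in turn gave 0 to 2451 risen and 0 to 1525 fallen genes, and 0 to 633 and 0 to 377 at least 2-fold. The zeros came without SKO 3. The 2-fold falls were 377 without CTL 1, 312 without CTL 2, 76 without CTL 3 and 99 without SKO 1. The 2-fold rises were 159 without CTL 3, 268 without SKO 1 and 286 without SKO 2. Lists called were 6 or 7 up and 5 to 7 down.

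The set calls are the least firm. With an estimated correlation 0 lists were called up and 0 down. The test fry, which asks for a change of the list itself and not relative to other genes, called 8 up and 3 down. Among them was the N6AMT1 and TRMT112 network (up), which the main set test does not call. The median of Y-linked genes lost its call with median-ratio factors (-0.35), Sertoli factors (-0.28), a mean of at least 1 CPM (-0.0061), the library set as a term (-0.20), the length and GC correction (-0.40), without the deepest libraries (-0.14) and with an estimated correlation (-0.30). It turned to 0.50 within the higher 18S libraries, and with 1 library left out ran from -0.60 to -0.18. Elongating spermatid genes turned to 0.18 within the higher 18S libraries. Without the deepest libraries they turned to 0.46 and round spermatid genes to 0.24.

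With the replicate number as a block 2162 genes rose and 1701 fell, the Y-linked median of -0.30 lost its call (adjusted p = 0.054), and 1 further list passed, the G2/M genes. Same-numbered libraries deviated together with correlations of 0.673, 0.012, 0.082 and 0.231, and CTL 1 alone correlated best with its own number. These values show no clear pairing by number. They cannot exclude it, since technical differences such as the library set also enter the deviations.

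Of the named genes called, 77 lost their call without SKO 3, 45 without CTL 3, 40 without SKO 1, 37 without SKO 2 and 28 with Sertoli factors. None that was called turned its direction, with directions under library totals and Sertoli factors taken relative to the median of all genes.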

Other observations

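Of the tests below, those written before their result was seen are the length and GC correction of the 3 patterns, the library set for the X-linked genes and the Sertoli covariate for the X-linked genes. All others were written after the pattern was seen, as were the split of the libraries by 18S and the bound of 50% of the size that decides the covariate and correction tests, which was set once the list medians were known.

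Heart muscle markers, included because a protocol line names heart ventricles, had 8 of 18 members in the table. Of these 2 rose and 0 fell, also when adjusted over the list alone (median log2 fold change 0.81; set test adjusted p = 0.0121, and adjusted p = 0.304 with an estimated correlation). Without the 2 most deeply sequenced libraries the list did not pass at a similar size (median 0.84, adjusted p = 0.111). Tnni3 went from 1391 ± 315 to 4041 ± 827 (SD, n = 4 each; limma adjusted p = 0.0123) and Tnnt2 rose 2.01-fold. Of 6 red blood cell markers 0 rose and 1 fell, also when adjusted over the list alone (median -0.18, set test adjusted p = 0.226), the X-linked haem synthesis gene Alas2 (2.07-fold lower), of whose exon bases 12.9% overlap Apex2. Of 14 epididymis and vas markers 2 were in the table and neither passed (median -0.85; exact permutation p of the score = 0.0286, n = 4 each). Rnase10 had means of 662 ± 187 and 451 ± 185 (SD, n = 4 each; limma adjusted p = 0.2). Of 12 mitochondrial genes 2 rose and 0 fell, with a median of 0.60, and their scores overlapped between the groups (exact permutation p = 0.2, n = 4 each). With the library set as a term 9 rose and the median was 0.84.

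Regrouping the 8 libraries into 4 and 4 can be done in 35 ways. Only the real grouping, 1 of 35, gave as many changed genes (3392, with at most 332 in the others), and the same held for genes changed at least 2-fold (1 of 35; 607, with at most 322 in the others). A share of 1 in 35 is the smallest that this test can give, so it argues against chance for these counts but does not exclude it. The next highest grouping, CTL 1, CTL 2, SKO 1 and SKO 2 against the rest, keeps the 3 libraries with more 18S together. For the number of lists called by camera chance cannot be excluded. 5 of 35 groupings called at least the 12 lists of the real one, and the highest of the others called 15. A grouping that puts CTL 3, CTL 4 and SKO 4 with CTL 1 called 13. With the library set as a term in the fit the real grouping called 7 lists up and 5 down.

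The higher Sertoli markers may reflect a difference in cell make-up. The Sertoli score rose by 0.64 more than the mean of the Leydig, endothelial, myoid and macrophage scores (exact permutation p = 0.028571, n = 4 each). That test assumes that a lower share of germ cells raises all somatic markers alike. The 4 comparison lists did not move alike, with median log2 fold changes of 0.21, 0.12, 0.49 and 0.65 in that order. It therefore does not decide about germ cell loss. With the library set as a term the median log2 fold change of the Sertoli list was 0.87558. After the length and GC correction it was 0.83411, against 0.93 before, so neither is the whole source. Open are a lower share of germ cells, a larger share of Sertoli cells, a change within them, and the genotype itself.

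The lower cilium and axoneme genes kept a median of -0.65187 with the library set as a term and of -0.81369 after the length and GC correction, against -0.74 before, so both are argued against as the whole source. A lower share of spermatids was tested in 3 ways. The first test compared the cilium score with the elongating spermatid score, and their difference of -0.45 did not separate the groups (exact permutation p = 0.57143, n = 4 each), which left the question undecided. The other 2 tests were chosen only after that result was seen. With the mean of both spermatid scores as a covariate the group difference of the cilium score was -0.84821, against -0.78 without it, and it stayed between -0.96 and -0.75 with any library left out. That fit leaves out the library set, which goes with the spermatid scores. With the library set as a further covariate the difference was -0.65379, against -0.68 with the set alone. It stayed between -0.72 and -0.55 with any library left out. Neither fit decides about spermatid loss. Spermatid scores were 0.73, 1.07, -0.17 and -0.95 in CTL 1 to 4, and cilium scores 0.13, 0.21, 0.71 and 0.51. Within CTL the cilium score was thus higher where the spermatid score was lower, which also follows the library set. With the set as a term, 8 libraries leave little from which to estimate the spermatid term. Rows that go with spermatid loss are the medians within the lower 18S libraries, -0.86 for round and -1.15 for elongating spermatid genes against -0.68 for cilium genes, and those with the set as a term, -0.56 and -0.66. Open are spermatid loss as a part or the whole of the source, and a change in spermatocytes, where these genes are also transcribed. The genotype itself is also open, as a hypothesis found and tested on the same 8 libraries.

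The X-linked minus autosomal median was 0.46. It was 0.46889 with the library set as a term and 0.48397 after the length and GC correction, which argues against both as the source. With the Sertoli score as a covariate it was 0.10496, and between 0.03 and 0.14 with any library left out. This is consistent with a larger share of Sertoli cells, which do not silence their X chromosome, as a candidate source. The covariate also separates the groups, and the cilium list and the retinoic acid list likewise brought the value below 50% of its size (0.15 and 0.22), so the test does not single out Sertoli cells, and weaker silencing in spermatocytes was not tested.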
